A study of Mus musculus with 6 samples.

How the data were processed

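RNA was measured in the distal tips of mouse limb buds, in 6 libraries of 2 pooled embryos each, 3 from embryos that overexpressed Meis2 and 3 from controls. Per the labels, polyA RNA was made into TruSeq RNA v2 libraries, and the submitters' processing notes name cutadapt 1.2.1, RSEM 1.17 and edgeR without a version, with genome build NCBIM37. The deposited table holds 12065 genes with Ensembl gene identifiers in CPM, the usual read count scaled for depth, which the authors computed on an effective library size. The notes state neither the filter on low genes nor the scaling factors.

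Every deposited value was tested against whole multiples of 1 step per library. The largest distance from a whole read was 3.06e-10, and 100% of the values lay within 0.001 of one, so whole reads were recovered for all 6 libraries. TMM factors computed from these reads gave the authors' effective sizes, with a ratio of 1 in every library. The third-highest of the 6 values was at least 2.00 CPM in every gene of the table, and the planned filter of at least 1 CPM in 3 libraries removed 0 genes. The depth behind the values was 7622700 to 15395400 recovered reads per library. A count of 0 in a library is read as an upper limit of 3 reads, which was 0.194 to 0.388 CPM, and this limit covers counting error only.

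The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(CPM + 1), with genotype as the only term, two-sided, over all 12065 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the log2 fold changes given are overexpression minus control with the standard error (SE) of the fit. Slopes per somite came from a fit with genotype and somite number, and an added interaction term tested whether the slopes differed between genotypes. Values of a group are means ± SD over 3 pools. An exact test of 3 pools against 3 cannot give a p below 0.1, so gene-wise tests rest on the spread that limma pools across genes, with 6.03 prior degrees of freedom.

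Before the data were examined, 29 gene lists were fixed: limb patterning genes of the proximal and distal mesenchyme, 5' Hoxa and Hoxd genes, 3' Hox genes and TALE homeobox partners; the retinoic acid pathway and genes induced by retinoic acid; FGF targets and feedback, FGF ligands and receptors, SHH and posterior limb, anterior limb, BMP, WNT, and Eph and ephrin genes; chondrogenesis, tendon and connective tissue, forelimb and hindlimb identity, cell cycle, p53 targets and cell death, and dissection and heat stress; and markers of ectoderm, muscle, endothelium, erythroid cells, macrophages, nerve, trunk mesoderm and sex. Meis2 was left out of all of them. The 27 lists with at least 3 measured genes were tested with camera on the same fit (preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry. Genes were named by a rule fixed at the same time: Meis2, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and separated genotypes, up to 4 called members of each list or else 2 with the smallest p, and the 5 genes with the smallest p in each direction of the stage slope, with unnamed gene models skipped. Members of a list discussed as a whole were given whatever their p, and any other gene is named as chosen after its values were seen.

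Near-identical copies were sought with blastn 2.17.0 among GENCODE M21 transcripts, at 97% identity or more over at least 100 bases and 50% of the shorter transcript. M21 held 11747 of the 12065 identifiers, and 1234 had such a copy. Genes with a copy and pseudogenes were tested with the others and are counted apart. No coordinates are given, because M21 uses a later build than the authors did.

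The alternatives were pseudocounts of 0.1 and 5, a stricter filter of 5 CPM (10652 genes left), median-of-ratios and quantile scaling, robust eBayes without a trend, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, somite number as a covariate, replicate number as a block, the slope without the genotype term, and each library left out in turn. Alternatives chosen after the data were seen were the sum of near-identical copies, the mean Y-linked level of each pool as a covariate, edgeR with the block, the count of genes without a copy and the interaction. The fit was tested on simulated tables of the same size, in which it recovered 60.9% of genes changed 1.5-fold, 90.4% of those changed 2-fold and 97.6% of those changed 4-fold, with 6.62% of calls false. Simulated tables without changes gave at most 3 called genes and 2 called lists. Their genes were drawn independently, so the list count leaves out correlation between genes. In the real libraries a split that did not follow the genotypes called as many as 10 lists.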

Results

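Gene expression was measured in the distal tips of limb buds from mouse embryos that overexpressed Meis2, a TALE-class homeobox gene that normally marks the proximal limb. The transgene, Meis2 isoform a followed by a fluorescent reporter in the Rosa26 locus, was activated by a tamoxifen-dependent Cre recombinase under HoxB6 control. Control embryos carried the same transgene without Cre, so effects of Cre itself are not separated from those of raised Meis2. The labels give a dose of 0.8 mg of 4-hydroxytamoxifen at embryonic day 8.3. Each genotype had 3 pools of 2 embryos, 1 pool each at 37, 38 and 39 somites, so the replicate number and the stage are the same thing. Control replicates 1 to 3 had 10605800, 11542200 and 8362850 recovered reads and the overexpressing ones 10741400, 7622700 and 15395400. The 10 most abundant genes took 4.59% to 4.95% of the reads of a library.

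The first comparison asked what raised Meis2 does to the distal limb, in a series on how Meis genes act through retinoic acid and FGF signalling. Meis2 mRNA rose 2.07-fold, from 16.6 ± 3.61 CPM (SD, n = 3) to 34.3 ± 6.62 CPM (n = 3), and was higher in the overexpressing pool at every stage. Tbx18, a T-box gene of the proximal limb mesenchyme, rose 3.11-fold, from 9.62 ± 1.90 to 29.9 ± 8.58 CPM. Fgf8, the main FGF ligand of the apical ridge, which is the signalling epithelium at the limb's edge, fell from 94.6 ± 5.35 to 56.5 ± 10.2 CPM. Of the 27 gene lists tested with camera, 5 were higher (proximal limb mesenchyme, retinoic acid pathway, tendon and connective tissue, endothelium, erythroid cells) and 4 were lower (ectoderm, FGF ligands and receptors, BMP pathway, p53 targets). With an estimated correlation 1 of these calls held, that of the ectoderm markers (adjusted p = 0.0312).

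Of 12065 genes tested with limma, 95 rose and 82 fell, and 34 of the rises and 13 of the falls were at least 2-fold. All 177 called genes had genotypes that did not overlap, which held for 20.7% of all genes (2502) against 10% by chance. Among the 10465 genes without a near-identical copy, 71 rose and 62 fell. The count over all genes was 340 with somite number as a covariate, 290 with DESeq2 and 86 with robust eBayes without a trend. It was 90 without control replicate 2, 64 without control replicate 3, 115 without overexpressing replicate 1 and 56 without overexpressing replicate 2.

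Col12a1, a collagen associated with fibrils, rose from 1.53 ± 0.826 to 8.88 ± 4.40 CPM (log2 fold change 1.92, SE 0.35, adjusted p = 0.0297). Mab21l1 rose by 1.71, Rspo4, a secreted enhancer of WNT signalling, by 1.54, Tbx18 by 1.52, and Dock9 by 1.47 on the log2 scale. Igf1, the insulin-like growth factor, rose 2.61-fold, from 4.96 ± 0.871 to 12.9 ± 1.15 CPM (adjusted p = 0.00207), and was called in all 19 fits tried. Hddc3 (log2 fold change 1.22) and Hbb-b2, an adult beta globin (1.09), completed the named rises together with Rpl35a-ps2 and Srp54a. Srp54a rose by 2.25 under an identifier that GENCODE M21 lacks, so near-identical copies could not be sought for it. Its level in control replicates 1 to 3 was 11.5, 6.02 and 28.9 CPM. Among genes without a copy the steepest falls were those of Aox3, an aldehyde oxidase, from 14.8 ± 2.78 to 6.19 ± 2.00 CPM (log2 fold change -1.15, SE 0.20, adjusted p = 0.0236), and of Eps8, an actin regulator, at -0.99. Pmaip1, which encodes the pro-apoptotic protein Noxa, fell by 0.94 on the log2 scale, Myo7a, an unconventional myosin, by 0.93 and Scn4b, a sodium channel subunit, by 0.86. Pcsk6, a protease that activates TGF-beta family ligands and has a near-identical copy, fell by 0.97.

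Genes with a near-identical copy and pseudogenes made up 24 of the 47 genes changed at least 2-fold. Of 216 annotated pseudogenes, 22 were called (12 higher, 10 lower). After the values were seen, 18 gene models were found with at least 2 CPM in each library of 1 genotype and under 1 CPM in each of the other, 12 in overexpressing tips and 6 in controls. They were 17 pseudogenes and 1 model that M21 lacks. Gm8730 was assigned 0 reads in the 3 control libraries and 7657 in the overexpressing ones, at least 2288-fold more with the floor of 3 reads taken over the group. That floor covers counting error and not the assignment of reads between copies. Its near-identical copy Rplp0 went from 1362 to 1121 CPM. The sum of Rplp0, Gm8730 and Gm14165 was 1362 ± 170 CPM in controls and 1351 ± 34.1 CPM in overexpressing tips. Rpl35a-ps2 had 1 read against 1687, and Rbpsuh-rs3 had 448 reads in controls against 8. The ribosomal protein gene Rpl29 fell from 441 ± 39.5 to 238 ± 7.42 CPM while its pseudogene Gm13841 went from 0.351 to 213 CPM, and the sum of both was 442 ± 39.4 and 451 ± 10.9 CPM. Tdg, a DNA glycosylase, rose from 174 to 259 CPM while Gm9855 and Gm5806 fell, with a sum of 249 ± 9.69 and 259 ± 9.25 CPM. Tuba1c, a tubulin, and Amd2, an enzyme of polyamine synthesis, also have copies and fell by 1.31 and 2.09 on the log2 scale.

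**Figure D1:**
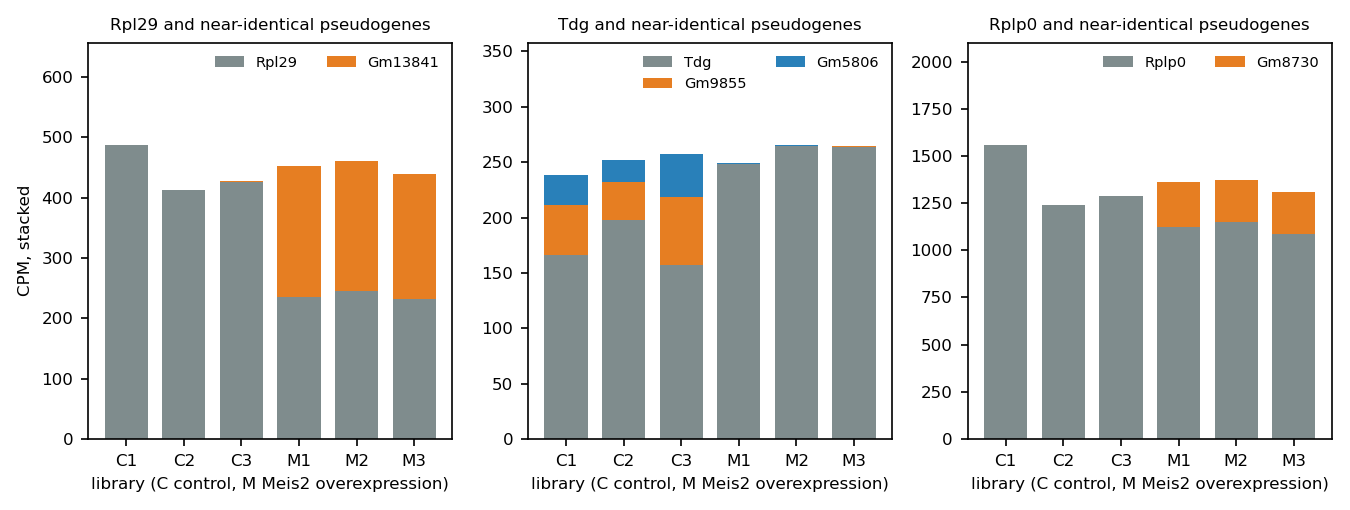
Stacked level in CPM of Rpl29, Tdg and Rplp0 and of near-identical pseudogenes (colours) in each control (C) and overexpressing (M) library. The pseudogene part is visible in 1 genotype only in each panel, while the summed Rpl29 level was 442 CPM in controls and 451 CPM in overexpressing tips.

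Genes of the proximal limb mesenchyme rose as a group by camera at the preset correlation, but not by fry (adjusted p = 0.161). Of 12 measured, 3 rose, 0 fell and 9 did not pass; adjusted over the list alone, 6 were higher (camera adjusted p = 0.00218; adjusted p = 0.247 with an estimated correlation). Besides Tbx18, the called genes were Pkdcc, a secreted tyrosine kinase of skeletal development (log2 fold change 1.74, from 1.38 to 7.65 CPM), and Zbtb16, a zinc finger gene of skeletal patterning (0.70). Shox2, a homeobox gene of the upper limb skeleton, stood at 104 ± 39.2 CPM (SD) against 44.2 CPM in controls, which did not pass (adjusted p = 0.113). It passed with somite number in the fit (adjusted p = 4.91e-05) and in some other alternatives, such as that without overexpressing replicate 3 (4.91e-05 to 0.292 over all of them). Meis1, the closest relative of Meis2, differed by 0.09 (SE 0.18). In the same libraries all 26 ectoderm markers were lower (median -0.44), and all 14 erythroid markers and 13 of 14 endothelial ones were higher.

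Genes of the distal mesenchyme did not pass as a group in the fit by genotype alone. None of the 16 measured was called over all genes or adjusted over the list alone, 6 were higher and 10 lower, and their median log2 fold change was -0.18 (camera adjusted p = 0.385). Sall4 and Mycn had the smallest p of the list, at 0.31 and 0.18. The 5 lowest, picked out after their values were seen, were Evx2 (-0.86), Hoxa13 (-0.78), Hoxd13 (-0.74), Tcfap2b (-0.68) and Jag1 (-0.65), while Lmo1 (0.29) and Lhx2 (0.24) were higher and Lhx9 was at -0.01. With somite number in the fit 6 of the 16 fell and the group passed (camera adjusted p = 0.00272; adjusted p = 0.366 with an estimated correlation). Over all alternatives the group's adjusted p ran from 7.17e-06 to 0.898.

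The 5' Hoxa and Hoxd genes, which pattern the limb from shoulder to digits, did not pass as a group in that fit. None of 10 passed over all genes; adjusted over the list alone, 1 was higher and 3 were lower (camera adjusted p = 0.218). Hoxd9 was 0.51 higher, Hoxa9, Hoxa10, Hoxa11 and Hoxd10 lay between -0.06 and 0.06, and Hoxd11 (-0.30), Hoxd12 (-0.38), the antisense transcript Hoxa11as (-0.42), Hoxd13 and Hoxa13 were lower, the last at 87.0 ± 30.9 against 148 ± 41.1 CPM. With somite number in the fit, 1 of the 10 rose and 4 fell, and the group passed (camera adjusted p = 0.00802; adjusted p = 0.366 with an estimated correlation). Of 13 measured 3' Hox genes none was called over all genes or adjusted over the list alone (adjusted p = 0.959); their median was -0.03 and their mean 0.02, and Hoxd4 and Hoxd8 were at 0.53 and 0.23. The 8 TALE homeobox partners had no call by either adjustment (adjusted p = 0.218), with Tgif2 at 0.15 and Pbx3 at 0.23.

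**Figure D2:**
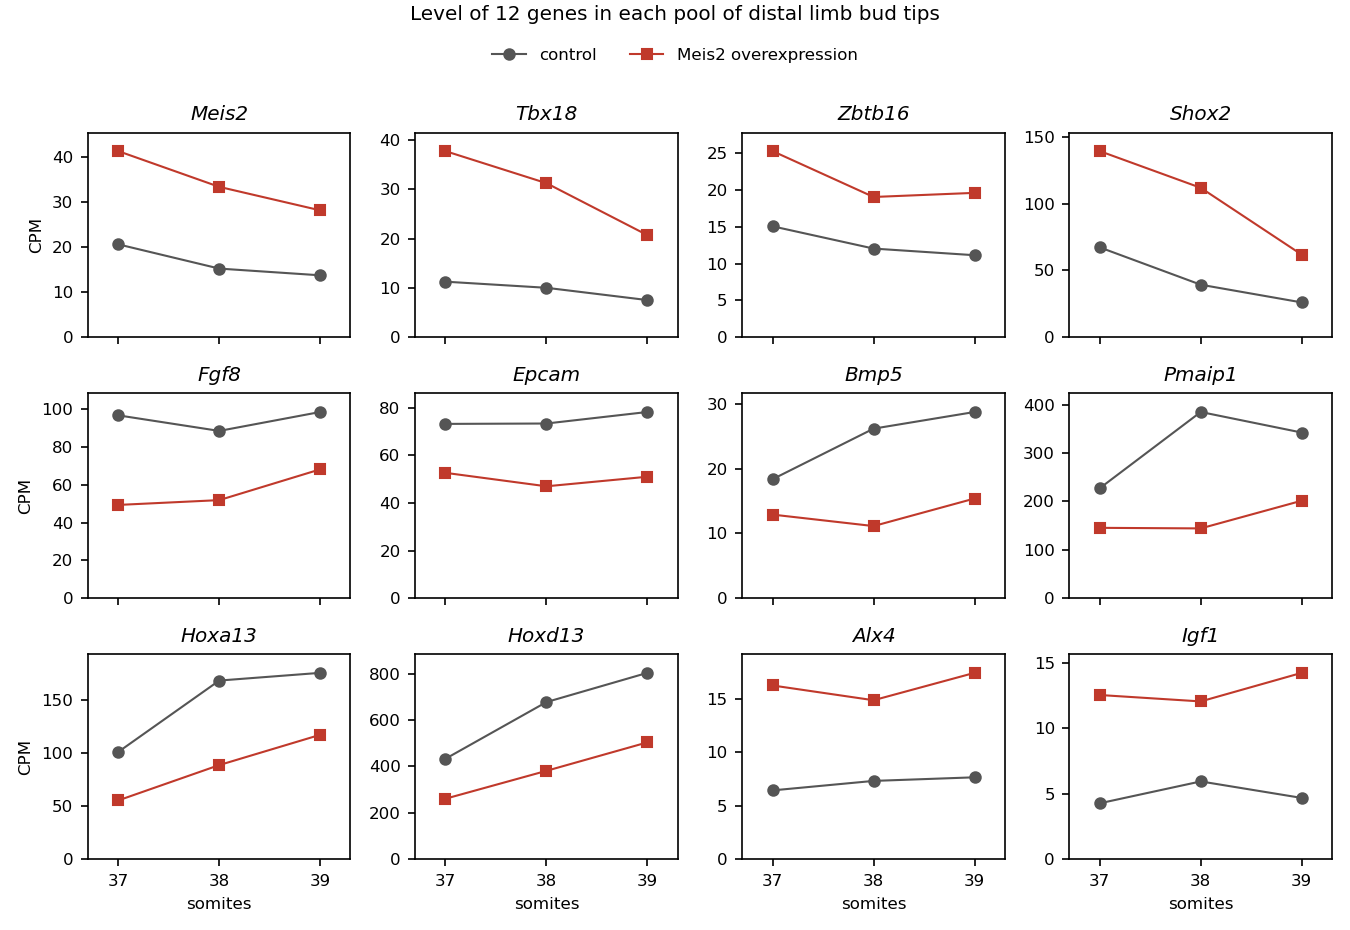
Level in CPM (vertical axes, starting at 0) of 12 genes against somite number, with 1 point per pool of 2 embryos, controls as grey circles and overexpressing pools as red squares. Meis2 lay between 28.2 and 41.3 CPM in overexpressing pools and between 13.8 and 20.6 CPM in controls, and the lines of the genotypes do not cross in any panel.

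The retinoic acid pathway, which carries the signal from the trunk and proximal limb, was higher as a group in these tips with lower ectoderm and higher blood markers. None of its 12 measured genes was called over all genes, and 4 were higher when adjusted over the list alone (camera adjusted p = 0.0307; adjusted p = 0.247 with an estimated correlation). By sign 8 were higher and 4 lower. The 4 lower, named after their values were seen, were Cyp26a1 (-0.28), Dhrs3 (-0.24), Rdh10 (-0.21) and Cyp26b1 (-0.21), none of them called. Stra6, the membrane receptor for retinol uptake, had 2.05 times its control level of 9.28 ± 1.34 CPM (log2 fold change 0.93, adjusted p = 0.0504), and Crabp2, a carrier of retinoic acid, had a log2 fold change of 0.36 (with somite number in the fit both passed, adjusted p = 0.0187 and 0.0127). The group missed the threshold with robust eBayes without a trend (adjusted p = 0.0818) and without control replicate 2 (median log2 fold change 0.12), in a range of 0.00460 to 0.0818 over the alternatives. Genes induced by retinoic acid, a list that shares genes such as Stra6, Crabp2 and Rara with the pathway, had no call over all genes among 10 and 5 higher when adjusted over the list alone (camera adjusted p = 0.0781, or 0.0494 with somite number in the fit and 0.278 there with an estimated correlation). By sign 6 of these 10 were higher and 4 lower, and Cyp26a1, Dhrs3 and Cyp26b1 were among the lower.

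The FGF ligands and receptors fell as a group, in tips where all 26 ectoderm markers were lower. Of 8 measured, 3 fell, 0 rose and 5 did not pass; adjusted over the list alone, 4 were lower and 1 was higher (camera adjusted p = 0.00254; adjusted p = 0.241 with an estimated correlation). The 3 that fell are ligands of the apical ridge: Fgf8 (log2 fold change -0.75, SE 0.11, adjusted p = 0.0114), Fgf4 (-0.83) and Fgf9 (-0.77). Fgf10, the ligand of the mesenchyme, was at 69.8 ± 1.83 against 72.7 ± 1.27 CPM, and the receptor Fgfr1 was 0.32 higher (adjusted p = 0.0827). The 14 FGF targets and feedback regulators had no call over all genes or adjusted over the list alone, with a median of -0.07 (adjusted p = 0.218). Dusp4 and Dusp6, phosphatases induced by FGF signalling, were at -0.45 and -0.27 (adjusted p = 0.0459 and 0.0540 with somite number in the fit).

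Markers of the ectoderm and apical ridge were lower in all 26 cases, with a median log2 fold change of -0.44. Of these, 10 fell, 0 rose and 16 did not pass; adjusted over the list alone, 20 were lower (camera adjusted p = 1.59e-18; adjusted p = 0.0312 with an estimated correlation, or 0.132 with somite number in that fit). Epcam, an epithelial adhesion molecule, fell from 74.9 ± 2.84 to 50.2 ± 2.91 CPM (adjusted p = 0.00332). E-cadherin (Cdh1) fell by 0.50 and Trp63, the p63 regulator of stratified epithelium, by 0.48 on the log2 scale. The list includes the ridge ligands Fgf8, Fgf4 and Fgf9 described with the FGF genes. The 14 markers that are not ridge genes had a median of -0.43 and the 12 ridge genes a median of -0.47.

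In the same tips, where ectoderm markers were lower, genes of the BMP pathway fell as a group, with 2 of 15 lower, 0 higher and 13 not passing, and 2 lower when adjusted over the list alone (camera adjusted p = 0.00429; adjusted p = 0.247 with an estimated correlation). The 2 were Bmp5, from 24.4 ± 5.40 to 13.1 ± 2.14 CPM, and Bambi, a pseudoreceptor that dampens TGF-beta signals (-0.48). Of 19 WNT pathway genes Sfrp2, a secreted modulator, rose (0.68), Notum, a WNT deacylase, fell (-0.66), Rspo2, an enhancer made by the ridge, fell (-0.73) and 16 did not pass; adjusted over the list alone, 2 were higher and 6 lower (camera adjusted p = 0.276). Of 5 anterior limb genes Alx4, a repressor of posterior fate, rose from 7.14 ± 0.633 to 16.2 ± 1.28 CPM (log2 fold change 1.08, adjusted p = 0.00129), as the 1 higher gene also when adjusted over the list alone (camera adjusted p = 0.0781). Among 12 SHH and posterior limb genes none was called over all genes or adjusted over the list alone (camera adjusted p = 0.0705; with somite number in the fit 1 fell and the group passed as lower at 0.0157, or 0.555 with an estimated correlation), with Shh at 24.2 ± 4.13 against 36.5 ± 9.86 CPM and Hoxd11 at -0.30. The Eph and ephrin genes had no call among 19 and 2 higher when adjusted over the list alone (camera adjusted p = 0.276), Epha7 at 0.62 (adjusted p = 0.0153 with somite number in the fit) and Ephb6 at 0.42.

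Connective tissue genes rose as a group by camera, in libraries with lower ectoderm and higher blood and vessel markers. Fry did not call them (adjusted p = 0.0857). Of 8 tendon and connective tissue genes 2 rose, 0 fell and 6 did not pass, and 3 were higher when adjusted over the list alone (camera adjusted p = 0.000738; adjusted p = 0.247 with an estimated correlation). The 2 were the type I collagen genes Col1a2 (0.48) and Col1a1 (0.57). The 10 chondrogenesis genes had no call over all genes, with 1 higher and 1 lower when adjusted over the list alone (adjusted p = 0.957): Sox9, the regulator of cartilage fate, at 0.86 (adjusted p = 0.0227 with somite number in the fit) and Hapln1, a cartilage link protein, at -0.41. The p53 targets and cell death genes fell as a group, with Pmaip1 as the 1 called gene of 12 and 4 lower when adjusted over the list alone (camera adjusted p = 0.00429; adjusted p = 0.247 with an estimated correlation).

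Markers of blood and vessels were higher in the same libraries. Of 14 erythroid genes, 3 rose, 0 fell and 11 did not pass, and adjusted over the list alone 11 were higher (camera adjusted p = 1.87e-10; adjusted p = 0.247 with an estimated correlation). The embryonic alpha globin Hba-x rose from 559 ± 122 to 892 ± 107 CPM, Slc4a1, the red cell anion exchanger, by 0.65 and Hbb-b2 by 1.09 on the log2 scale. Of 14 endothelial genes Kdr, a VEGF receptor, rose (0.46) and 13 did not pass, and 3 were higher when adjusted over the list alone (camera adjusted p = 0.000294; adjusted p = 0.241 with an estimated correlation).

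The remaining lists had no call over all genes or adjusted over the list alone. The 28 cell cycle genes lay between -0.18 and 0.26 (adjusted p = 0.905), with Ccne1 highest (adjusted p = 0.0464 with somite number in the fit) and Top2a at -0.17. Forelimb identity (3 genes, Tbx5 at 0.17, adjusted p = 0.959) and hindlimb identity (6 genes, Tbx4 at 0.18, adjusted p = 0.577) did not pass. Neither did the dissection and heat stress genes (6 genes, Egr1 at 0.40, adjusted p = 0.905, with a median of -0.00 and a mean of 0.04), macrophage markers (6 genes, Cx3cr1 at 0.23, adjusted p = 0.905), or nerve and neural crest markers (4 genes, Erbb3 at -0.32, adjusted p = 0.218). Chrna1 (-0.36) was the 1 muscle marker measured, and Meox1 (-0.35) and Foxc2 (-0.22) were the 2 of trunk mesoderm. The 5 genes that mark the sex of the embryos did not pass (adjusted p = 0.152, or 0.0227 as lower with somite number in the fit and 0.366 there with an estimated correlation). Their levels differed between pools: the mean Y-linked level was 22.4, 42.3 and 44.0 CPM in control replicates 1 to 3 and 0.0701, 27.9 and 65.3 CPM in overexpressing replicates 1 to 3.

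**Figure D3:**
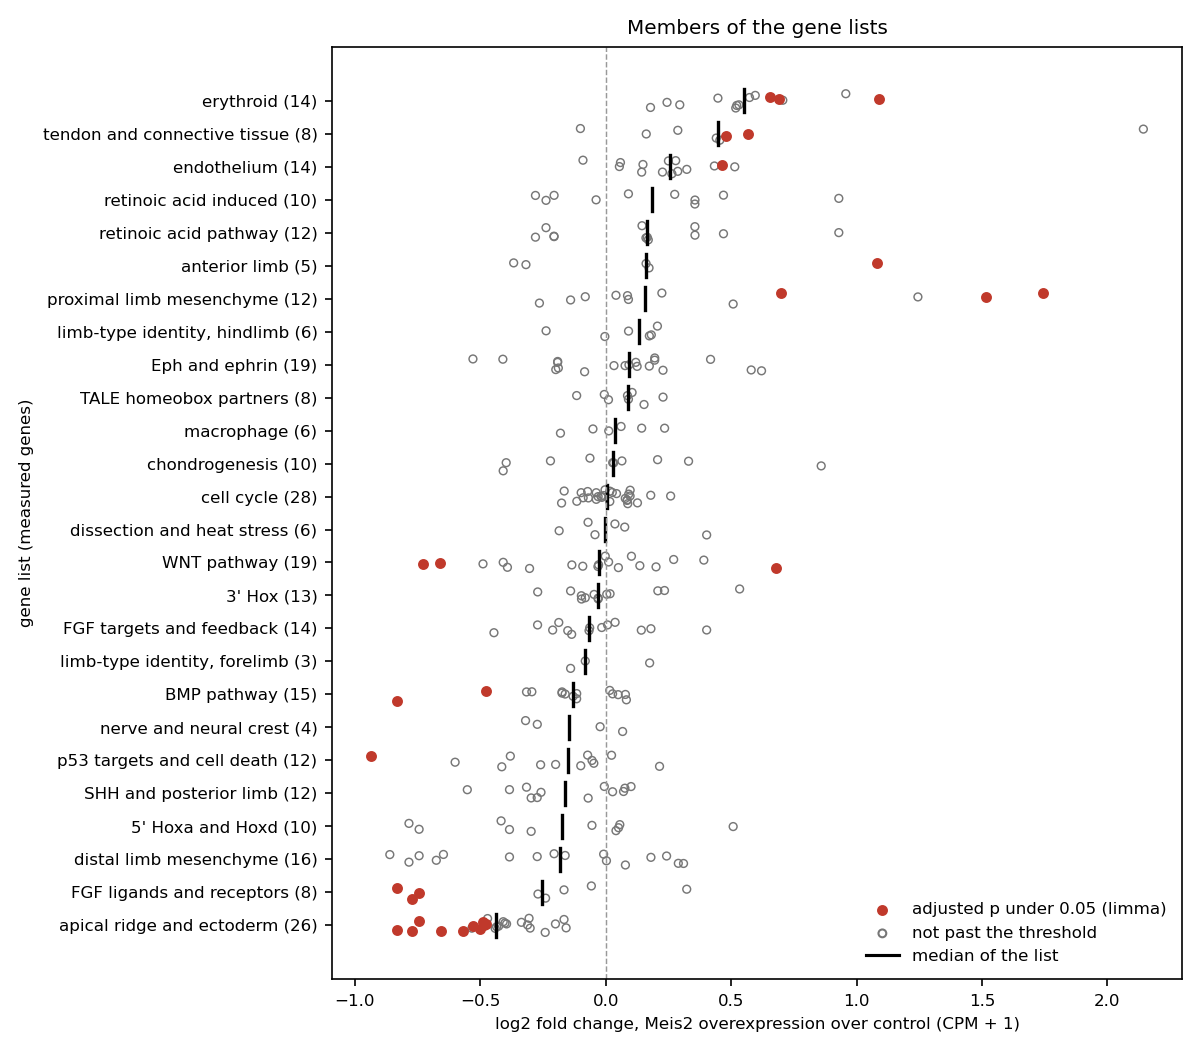
Log2 fold change (horizontal axis, overexpression over control) of each measured member of 26 gene lists, ordered by the median of the list (black bar), with called genes in red and the others as open circles. All 26 ectoderm markers lie below 0 and all 14 erythroid markers above it.

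The second comparison asked which genes follow the somite stage in both genotypes. Genes of the distal limb rose from 37 to 39 somites: Tcfap2b, a transcription factor of the distal mesenchyme, by 0.67 (SE 0.06), Evx2 by 0.80 (SE 0.08), the Notch ligand Jag1 by 0.53 and Hoxd13 by 0.46 per somite on the log2 scale. Shox2 fell by 0.62 (SE 0.05) per somite. Hoxa13 (0.47), Hoxd12 (0.33) and Hoxa11as (0.34) rose as well. The Y-linked level also rose with stage, from 22.4 to 44.0 CPM in controls and from 0.0701 to 65.3 CPM in overexpressing pools, and Xist, the transcript of the inactive X, fell from 1276 to 682 CPM and from 2051 to 34.3 CPM. Stage and the sex of the embryos are therefore not separated in either genotype.

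In all, 31 genes rose and 12 fell with stage (limma, 43 of 12065), and 22 and 7 of the genes without a copy. Of the 16 distal genes 6 rose and 0 fell, of the 12 proximal genes 0 rose and 1 fell, and none of the 26 ectoderm markers passed. Dgkk, a diacylglycerol kinase, was the other of the 5 named rises (0.54). The other named falls were Slitrk6 (-0.82), Dcx, a microtubule protein of neurons (-0.46), the transcript Dnm3os (-0.42) and the collagen gene Col3a1 (-0.34). Robust eBayes without a trend (limma) called 0 genes for the slope, with 859 at an unadjusted p under 0.05, edgeR called 42 and DESeq2 74, and limma called 2 with the Y-linked level of the pools as a covariate. It was 1 without overexpressing replicate 3, 17 without control replicate 3, 26 without control replicate 1 and 69 without control replicate 2.

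The third comparison asked whether the stage slope differed between the genotypes. Limma called 0 genes (240 at an unadjusted p under 0.05) and edgeR called 0 (248). DESeq2 called 3 (70 at an unadjusted p under 0.05): Gm8116 and the Y-linked genes Eif2s3y and Kdm5d, whose levels go with the sex of the pooled embryos.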

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

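The settings chosen after the data were seen were the Y-linked covariate, edgeR with the block, the sum of near-identical copies, the count of genes without a copy and the interaction. Scaling (median-of-ratios, quantile, DESeq2 size factors in edgeR), a pseudocount of 0.1 and the stricter filter kept each count within 1.5 times its value in the report. With a pseudocount of 5 the 2-fold count was 24. Robust eBayes without a trend gave 86 genes, 58 without a copy and 0 with a stage slope (859 at an unadjusted p under 0.05; edgeR 42, DESeq2 74). Somite number as a covariate gave 340 genes, 267 without a copy and 14 lists, and it kept all 177 genes. DESeq2 gave 290 genes (168 of the 177), 232 without a copy, 74 with a stage slope and 3 with an interaction. The slope count was 2 with the Y-linked covariate and 0 in limma with the genotype term left out (456 at an unadjusted p under 0.05). Camera with an estimated correlation called 1 list. Fry called 7, with genes induced by retinoic acid (adjusted p = 0.0434) but not the proximal (0.161), connective tissue (0.0857) and erythroid (0.0903) lists. Summing near-identical copies gave 238 of 11856. The cause of these shifts was not tested. The fit without any filter was void, since the planned filter removed 0 genes.

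Without 1 library, the count of genes changed by Meis2 overexpression ranged from 56 (without overexpressing replicate 2) to 162, with 64 and 90 without control replicates 3 and 2 and 115 without overexpressing replicate 1. Genes without a copy ranged from 27 to 120 (32, 50 and 79 without the same 3), 2-fold genes from 29 (without overexpressing replicate 2) to 57, and lists from 9 to 15 (without overexpressing replicate 3). Slopes ranged from 1 (without overexpressing replicate 3) to 69 (without control replicate 2), with 17 and 26 without control replicates 3 and 1. Of the 177 genes 54 to 119 were still called and 0 changed sign. Without overexpressing replicate 1, uncalled genes turned positive: Foxc2 0.16 (lowest -0.46 without replicate 3), Eif2s3y 0.24 (lowest -2.68) and Kdm5d 0.26 (lowest -2.66). Each of these fits has fewer samples, and depth (7622700 reads at the lowest) limits genes of few CPM.

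With replicate number as a block, limma gave 258 genes (157 of the 177), 61 at 2-fold, 193 without a copy and 13 lists, and edgeR with the block gave 73 at 2-fold and 14 lists. Same-numbered pools share a stage but no embryos or labelled batch. Their log2 levels correlated at 0.980, 0.978 and 0.983. Their deviations from each gene's group mean correlated at 0.03, -0.15 and 0.38. By these deviations each sample's best match in the other genotype was its own number for replicate 3 alone.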

Other observations

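All tests in this part were chosen after the results were seen, and so were the genes named outside the fixed lists.

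Receptors of hedgehog signalling rose in overexpressing tips although the SHH list had no call. Cdon rose from 27.9 ± 2.24 to 39.1 ± 1.43 CPM (SD, n = 3; limma adjusted p = 0.0226), Boc from 19.1 ± 0.366 to 28.8 ± 1.87 CPM (adjusted p = 0.0115) and Gas1 from 61.0 ± 6.31 to 87.0 ± 10.3 CPM (adjusted p = 0.0388). All are co-receptors that bind SHH at the cell surface. Lmx1b, the selector gene of the dorsal limb, rose from 91.1 to 125 CPM (log2 fold change 0.46, adjusted p = 0.0413).

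The red cell genes Hemgn (0.92), Ank1 (0.76), Kel (0.79) and Car2 (0.58) and the endothelial genes Stab2 (1.02) and Sox7 (0.80) rose on the log2 scale, each higher in 3 of 3 overexpressing pools than in any control. Genotypes did not overlap for 20.7% of all genes, so this separation is no added evidence for genes picked by their rise. Dsg2, a desmosomal cadherin of epithelium, fell by 0.65.

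Ectoderm markers were lower in overexpressing tips, both the ridge genes and the rest of the list. The 14 markers that are not ridge genes were lower in 14 of 14 cases with a median of -0.431, which argues against a fall of ridge genes alone. These 14 were not chosen for absence from the ridge, so a smaller ridge could lower them too and is not separated from less ectoderm elsewhere. A delay of the tips as the whole cause is argued against because all 26 markers stayed lower at every delay tried between 0.53 and 1.59 somites (medians -0.54 to -0.47; highest fry adjusted p = 0.0188), although camera with an estimated correlation called the list at none of them (adjusted p = 0.124 to 0.142; 0.132 with somite number in the fit and no delay). The delays tried came from stage slopes that are not separated from the sex of the pools, and delays outside that range were not tested. The medians of ridge and other markers differed by -0.03 (permutation p = 0.62 across genes, which are not independent replicates). A lower share of ectoderm in the dissected tissue, by anatomy or by dissection, may account for the pattern, and a lower expression per ectodermal cell stays open, since a bulk measurement does not separate them.

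Of 12 proximal genes 3 were called higher (adjusted p = 0.247 for the list with an estimated correlation, 0.206 with somite number in the fit) and, with somite number in the fit, 6 of 16 distal genes lower, in the direction of a younger stage. Across all genes without a copy, called or not, the genotype difference and the stage slope had r = -0.26 (genes are not independent replicates). Of the 29 genes with a stage slope and no copy, 28 had a genotype difference against their slope, and so did 89 of the 133 called genes without a copy. This may reflect tips less advanced than their somite count, by 0.95 somites at the median (quartiles 0.53 and 1.59) of the 22 genes outside the proximal, distal, 5' Hox and ectoderm lists, or an action of Meis2 on the same genes. The counts and the delay rest on slopes from 1 pool per stage and genotype, which are not separated from sex. Limma called 0 slopes with robust eBayes without a trend and 0 with the genotype term left out, so the size of the delay is uncertain. After adding that delay the proximal list was called higher at 10 of 11 delays by camera (highest adjusted p = 0.0726), at all 11 by fry (highest adjusted p = 0.0446) and at none with an estimated correlation (lowest adjusted p = 0.231), and Tbx18 was called at all 11 (highest adjusted p = 0.0249), so a delay and a separate proximal effect cannot be told apart for the whole list. Meis1, which more proximal tissue in the dissection would raise, differed by 0.0902 (SE 0.178), too wide to decide, and Meis2 itself, the change that the design names, stays open beside both. The presence of Cre, which goes with raised Meis2, was not separated from it.

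Of the 18 gene models seen in 1 genotype only, 13 lie in 10 families with a near-identical copy in the table, and for the other 5 no exchange could be measured. In the 4 families in which the models made up at least 10% (Rpl29, Tdg, Rplp0 and Cyb5r4), the copies lost or gained 100% (SE 6.64) of what the models gained or lost, as reads of shared sequence assigned to different copies would give. This share is weighted by size and precision, so it rests mostly on Rpl29. The Cyb5r4 copy lost 10.6 CPM (SE 3.60) against a gain of 7.25 CPM. In all 4 families the copies moved the opposite way to the models. In the other 6 the share was 65% (SE 33.7), too wide to decide, and in 3 of them (Hnrnpf, Zbed4 and Ldhb) the copies moved the same way as the model. A single genome segment behind all 10 families is argued against by parents on 5 chromosomes. Chromosome 9 holds 4 of these parents, and a segment there behind a part of the families was not tested. Sequence differences between the strains of the genotypes and processing that differed between them cannot be told apart, since both follow the genotypes: other splits of the libraries gave at most 5 such models against 18.

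Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 177 genes and the highest other 5; at 2-fold 47 and 5; without a copy 133 and 0, each reached by 1 of the 10 splits. For gene lists 2 of the 10 splits reached the real 9, the other calling 10, with control replicates 1 and 3 and overexpressing replicate 3 on one side.

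Of the 133 called genes without a copy, 6 pairs lay within 2 measured genes of each other, against a median of 3 in random sets matched for level (permutation p = 0.117). The lowest adjusted p for an excess on a chromosome (hypergeometric test) was 0.0932, for chromosomes 9 and 6. They held 15 called genes against 7.65 expected and 14 against 6.64. Tbx18, Col12a1 and Bmp5 lie on chromosome 9, as do 4 parents of the pseudogene families. Pairs within 2 measured genes do not show a longer segment, so a segment that differs between the genotypes was not tested for these genes.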
